A study of Mus musculus with 12 samples.

How the data were processed

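Gene expression was measured on 12 Affymetrix whole-transcript arrays, 1 per sample. The samples were CD8α+-like dendritic cells, the culture equivalent of the conventional type 1 dendritic cell (cDC1) that cross-presents antigen from dead cells. Per the labels' protocols, mouse bone marrow was grown for 10 days with Flt3 ligand at 100 ng/ml. Per the series' design text, cells from wild-type (WT) mice or from mice homozygous for a gfp allele of Clec9a were either left untreated or kept with dead cells for 5 h. The CD24-high, CD11b-low, B220-negative cells were then sorted. Clec9a encodes DNGR-1, a C-type lectin receptor that binds actin filaments exposed by dead cells. The dead cells had received UVC at 240 mJ/cm2 and 24 h of further culture, per the labels' protocols.

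The deposited values are a linear intensity for each of 23238 rows (transcript clusters) on each array, with the scale read from the values themselves. RNA was purified on columns with DNase, reduced in ribosomal RNA and labelled with biotin by a whole-transcript sense protocol, per the labels' protocols. The genome build was mm8, per the submitters' processing notes. The software, background correction, summary method and normalization behind the deposited intensity values are not given in the sources used here. The medians and quartiles of the arrays differed, so the values had not been forced to one distribution. Scan dates and detection calls were not used here, and no batch could be tested.

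Gene names came from an annotation table of the array platform, updated through gene IDs to the RefSeq genes of GRCm38.p6. This assembly is not the build of the arrays, so it gave only names and the order of neighbouring genes, and no coordinates are printed. Of the rows, 14939 had 1 gene symbol (14884 matched to RefSeq by gene ID), 989 had several and 7310 were not in the gene table. The single-symbol rows covered 14807 genes. Where 131 genes had more than 1 row, gene lists and named genes used the row with the highest mean over all arrays.

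Groups were taken from the labels, with 3 arrays in each of 4 groups. Intensities were converted to log2(value + 16). The design fixed before the data were examined called for a log2 without a pseudocount. Between 434 and 846 rows per array lay below 1, down to 0.00024, where a plain log2 gives large differences between replicates of dim rows. The pseudocount of 16 was therefore chosen after the values were seen, and it understates the change of dim genes. Between 11.5% and 15.2% of the rows of an array lay below it. Plain log2 and pseudocounts of 1 and 64 were run as alternatives.

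All 12 arrays entered 1 linear model with a mean per group in limma 3.58.1 (lmFit and eBayes, R 4.3.3, two-sided). The comparisons were dead cells against untreated in each genotype and averaged over genotypes, genotype in each treatment and averaged over treatments, and the difference between the genotypes' responses. A row was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The genotype difference is always Clec9a gfp/gfp minus WT, and the treatment difference dead cells minus untreated. Arrays have no depth, and their number limits the precision. The smallest p that permutations of 3 against 3 arrays can give is 0.1, so adjusted p-values from limma are printed.

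Before the data were examined, 31 gene lists were fixed. They covered pathways of dendritic cell activation and dead cell handling, and markers of other cells that a sort of bone marrow cultures could hold. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. The genes named were also fixed by rule. They were Clec9a in every comparison and, among called single-symbol rows whose replicates did not overlap, the 10 largest rises and 10 largest falls of each comparison. For averaged comparisons the replicates had to be apart within both strata. Where under 5 rows passed, the 5 with the smallest p were added. From each list up to 4 members with the smallest p could be named. For the difference in response, the 5 genes called in either genotype with the largest difference were added.

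The test was checked on simulated data made from these arrays, with 200 of the 23238 rows changed. For the WT response it recovered 16% of changes of 0.5, 84.5% of changes of 1 and 97% of changes of 2 on the log2 scale. For the untreated genotype comparison the shares were 3%, 80.5% and 97.5%. For the difference in response they were 0%, 61.5% and 93.5%. The adjusted threshold is stricter where fewer rows change and looser where more do. These shares therefore hold for 200 changed rows and do not carry over to comparisons with far fewer or far more. Further alternatives were quantile normalization, a shift of the arrays to one median, removal of the dimmest 25% of rows, 1 row per gene, trended and robust eBayes, array weights, fits on only the arrays compared, the replicate number as a block, a 1.5-fold minimum and leaving out each array in turn. Added after seeing the data were the pseudocounts and the removal of 6577 rows with no gene and IDs below those of rows with a gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.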

Results

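The data were 12 expression arrays of sorted CD8α+-like dendritic cells grown from mouse bone marrow with Flt3 ligand. There were 3 arrays in each of 4 groups, formed by genotype (WT or Clec9a gfp/gfp, which lacks the dead cell receptor DNGR-1) and by treatment (untreated, labelled 0 h, or 5 h with UV-treated dead cells). Median intensity was 93.6 to 101 on the 6 untreated arrays and 77.9 to 85.9 on the 6 arrays with dead cells. The upper quartile was 396 to 437 without and 231 to 259 with dead cells, while the lower quartile was 30.3 to 35.9 on all 12. Across rows, log2 values correlated at r = 0.972 to 0.987 between arrays of the same group and at 0.971 to 0.987 between genotypes under the same treatment. Between treatments r was 0.862 to 0.885, and genes are not independent replicates. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure only the spread between these samples.

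Clec9a, the targeted gene, was read out first as a check of the genotype labels. Its intensity was 2625 ± 38.3 (SD, n = 3) in untreated WT cells and 1446 ± 65.8 (SD, n = 3) in WT cells with dead cells. In Clec9a gfp/gfp cells it was 2.68 ± 2.32 and 1.99 ± 1.78 (SD, n = 3 each), below the pseudocount of 16. The genotype difference on the log2(value + 16) scale was -7.15 ± 0.11 (SE) untreated (adjusted p = 9.87e-11) and -6.35 ± 0.11 with dead cells (adjusted p = 3.45e-10), and both understate the true ratio. With a plain log2, which is dominated by the spread of values near 0, the differences were -12.31 (adjusted p = 0.214) and -9.93 (adjusted p = 0.613). In WT cells Clec9a fell with dead cells by 0.85 on the log2 scale (SE 0.11, adjusted p = 5.05e-05).

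**Figure D1:**
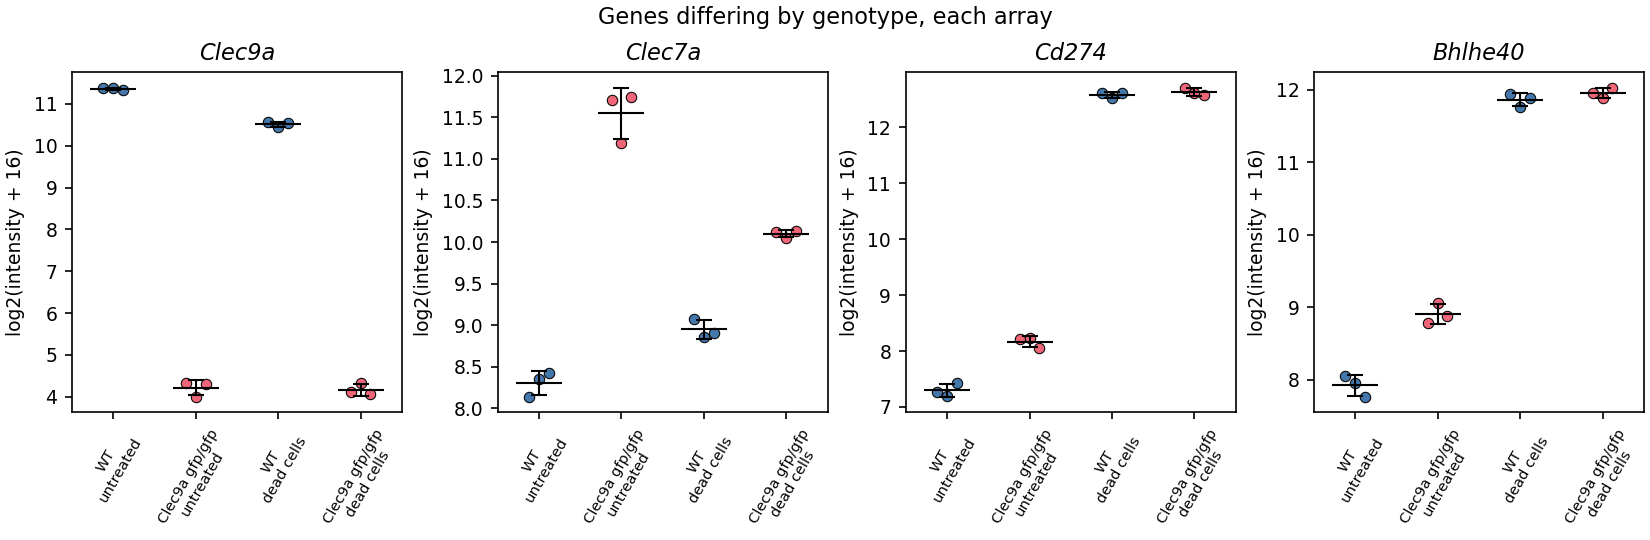
Each point is 1 array, on a log2(intensity + 16) axis, with bars for the mean and SD of 3 arrays in each genotype and treatment; the axes do not start at 0. Clec9a lies near the floor on all 6 Clec9a gfp/gfp arrays, and Clec7a intensity is 2310 to 3409 on the untreated Clec9a gfp/gfp arrays against 266 to 326.7 on the untreated WT arrays.

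The response of WT cells to dead cells was led by interferon-stimulated and maturation genes. All 31 measured interferon-stimulated genes rose, with a median log2 fold change of 2.99. Examples were Rsad2, an antiviral enzyme, at 7.08 ± 0.14 (SE), Oasl1 at a 128-fold change, Oasl2 at 4.80 ± 0.12 and Irf7, a transcription factor of the interferon response, at 4.54 ± 0.10. All 34 measured genes of dendritic cell maturation rose, with a median of 3.03. Among them were Cd40, a costimulatory receptor, at 5.50 ± 0.09, Cd274, which encodes the inhibitory ligand PD-L1, at 5.29 ± 0.09, Traf1 at 3.95 ± 0.10 and Stat5a at 3.43 ± 0.10. Of 46 inflammatory cytokines and NF-kB targets 33 rose and 6 fell (34 and 7 adjusted over the list alone), with Tnip3 at 4.90 ± 0.09 and Gadd45b at 3.79 ± 0.12. Of 25 hypoxia and glycolysis genes 18 rose and 3 fell (19 and 3 adjusted over the list alone), with Pfkfb3, an activator of glycolysis, at 2.81 ± 0.11 and Bnip3 at 2.69 ± 0.12. These 4 lists also held with an estimated correlation, at adjusted p = 0.00749, 0.00706, 0.00706 and 0.00706. For the lists called in either genotype's response, counts adjusted over the list alone equalled the counts over all rows except where given.

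The largest single rises in WT cells also included the interferon-induced genes Ifit2 (6.81 ± 0.30), Ifit1 (6.59 ± 0.31) and Gbp5 (5.68 ± 0.20), and Cxcl11 (6.27 ± 0.29), a ligand of Cxcr3. The nuclear receptor gene Nr4a3 (5.45 ± 0.17) and Mab21l3 (5.35 ± 0.23) completed the 10. Their adjusted p-values in limma ranged from 4.78e-11 for Oasl1 to 2.53e-08 for Cxcl11. Of 20 NRF2 targets of oxidative stress 12 rose and 4 fell, including Gclc at 3.31 ± 0.14, Srxn1 at 3.04 ± 0.14 and Hmox1 at 2.53 ± 0.13. Its call was lost with an estimated correlation, at adjusted p = 0.375.

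Cell cycle genes fell broadly. Of 24 S phase genes 23 fell, with a median of -2.30, and Mcm4, Mcm6 and Rrm1 changed by -3.22 ± 0.12, -3.11 ± 0.09 and -3.12 ± 0.10. Of 28 G2 and M phase genes 27 fell, with a median of -2.60, and Ccna2, the cyclin A gene, changed by -3.80 ± 0.12. Both calls had adjusted p = 0.33 with an estimated correlation. Of 19 cDC1 markers 14 fell and 2 rose. Tlr3, the receptor for double-stranded RNA, changed by -3.89 ± 0.14, Septin3 by -2.53 ± 0.11 and Naaa by -1.93 ± 0.08, while Ly75, which encodes the endocytic receptor DEC-205, rose by 3.06 ± 0.09. Of 21 LXR targets and cholesterol efflux genes 16 fell and 4 rose, and the lipid synthesis genes Scd2, Fads1 and Fasn changed by -2.98 ± 0.14, -2.66 ± 0.12 and -2.03 ± 0.11. With an estimated correlation the adjusted p was 0.566 for cDC1 markers and 0.375 for LXR targets.

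Markers of other cells were lower in the same arrays. Whether a smaller share of such cells contributed to the falls of cell cycle genes and LXR targets was not tested. Of 19 monocyte and macrophage markers 17 fell, with a median of -3.08, including Csf1r, C1qc, Selenop and C1qb at -3.91 ± 0.18, -3.70 ± 0.19, -3.53 ± 0.17 and -3.29 ± 0.15. Of 27 fibroblast and stromal markers 24 fell, with a median of -2.28, including Fstl1 at -2.91 ± 0.22 and Sparc at -2.54 ± 0.22. With an estimated correlation the adjusted p was 0.332 for the macrophage list and 0.648 for the stromal list. Of the macrophage list's genes 5 are also in another list, of the cDC1 list's 2 and of the stromal list's 0. Among the largest single falls in WT cells, S100a8, abundant in neutrophils and monocytes, changed by -5.09 ± 1.14, the mast cell protease gene Cpa3 by -4.79 ± 0.41, the scavenger receptor gene Stab1 by -4.55 ± 0.18, the mannose receptor gene Mrc1 by -4.35 ± 0.24 and F13a1 by -4.28 ± 0.14. Cxcr3 (-4.58 ± 0.20), Nxpe5 (-4.44 ± 0.14), Fcrls (-4.38 ± 0.18), Lbh (-4.31 ± 0.27) and Mlec (-4.15 ± 0.16) completed the 10.

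**Figure D2:**
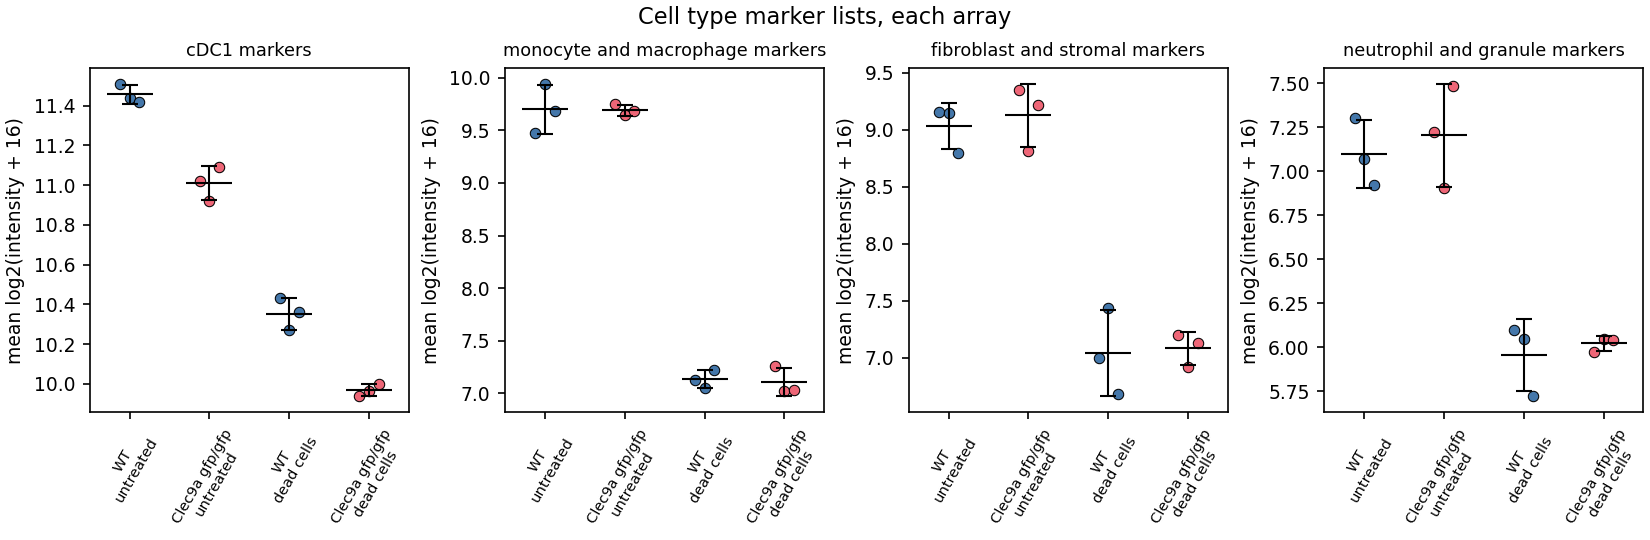
Mean log2(intensity + 16) of the members of 4 marker lists on each array (points), with the mean and SD of 3 arrays per group; the axes do not start at 0. Stromal markers average 9.04 in untreated WT cells and 7.04 in WT cells with dead cells, and the cDC1 list, which holds Clec9a, is lower in Clec9a gfp/gfp cells.

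The remaining lists were not called in WT cells. Among lists of cell function, immediate early genes had 13 rising and 13 falling members of 32 (14 and 13 adjusted over the list alone, as for each pair in brackets here), with Nr4a3 up and Dusp6 at -3.98 ± 0.14. Cholesterol synthesis had 4 rising and 12 falling of 21 (4 and 13), receptors and bridging molecules for dead cells 7 and 16 of 33 (8 and 16), and lysosome and phagosome 10 and 20 of 39 (11 and 21). In the receptor list Havcr1 (3.48 ± 0.16), Timd4 (3.13 ± 0.13) and Axl (2.77 ± 0.10) rose, while Stab1 changed by -4.55 ± 0.18. MHC class I presentation had 8 rising and 8 falling members of 22 (10 and 8), MHC class II presentation 1 and 2 of 9 (1 and 2), and Syk signalling 7 and 12 of 24 (7 and 13). Neighbours of Clec9a in the natural killer gene complex had 5 and 9 of 25 (5 and 10). The unfolded protein response had 9 and 8 of 29 (9 and 8) and heat shock 5 and 5 of 13 (5 and 5), with Hspa1a at 4.99 ± 0.14. The p53 targets had 4 and 12 of 22 (6 and 13), and glucocorticoid and TGF-beta responsive genes 4 and 7 of 17 (4 and 7). Among cell type lists, pDC markers had 6 rising and 7 falling of 17 (6 and 8), CD11b+ dendritic cell markers 5 and 10 of 21 (7 and 10), and neutrophil markers 0 and 8 of 18 (0 and 8). B cell markers had 0 and 6 of 14 (0 and 6), T and NK cell markers 4 and 3 of 19 (4 and 3), and erythroid, mast cell, basophil and eosinophil markers 2 and 7 of 18 (2 and 7). Melanocyte and epithelial markers had 3 and 0 of 16 (1 and 0), and ribosomal proteins with other reference genes for RNA quality 0 and 8 of 13 (0 and 9), with a median of -0.40. These balances depended on the scaling. With quantile normalization 12 rose and 14 fell among receptors for dead cells, 15 and 14 among lysosome and phagosome, 15 and 7 in the unfolded protein response and 7 and 3 among T and NK cell markers. The adjusted p of these lists on the deposited scale was 0.0553 or higher. Median, mean and test differed in sign for immediate early genes, lysosome, both MHC lists, Syk signalling, the neighbours of Clec9a, heat shock, glucocorticoid and TGF-beta responsive genes, and pDC, T and NK, and erythroid markers.

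In all, 3368 rows rose and 7213 fell in WT cells, of which 922 and 4385 changed at least 2-fold. Quantile normalization moved the median of all rows by 0.15 and gave 6277 rises and 5635 falls. A shift of each array to one median moved it by 0.22 and gave 6969 and 6264. Since the untreated cells are labelled 0 h, the comparison joins the effects of the dead cells and of 5 h in culture.

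**Figure D3:**
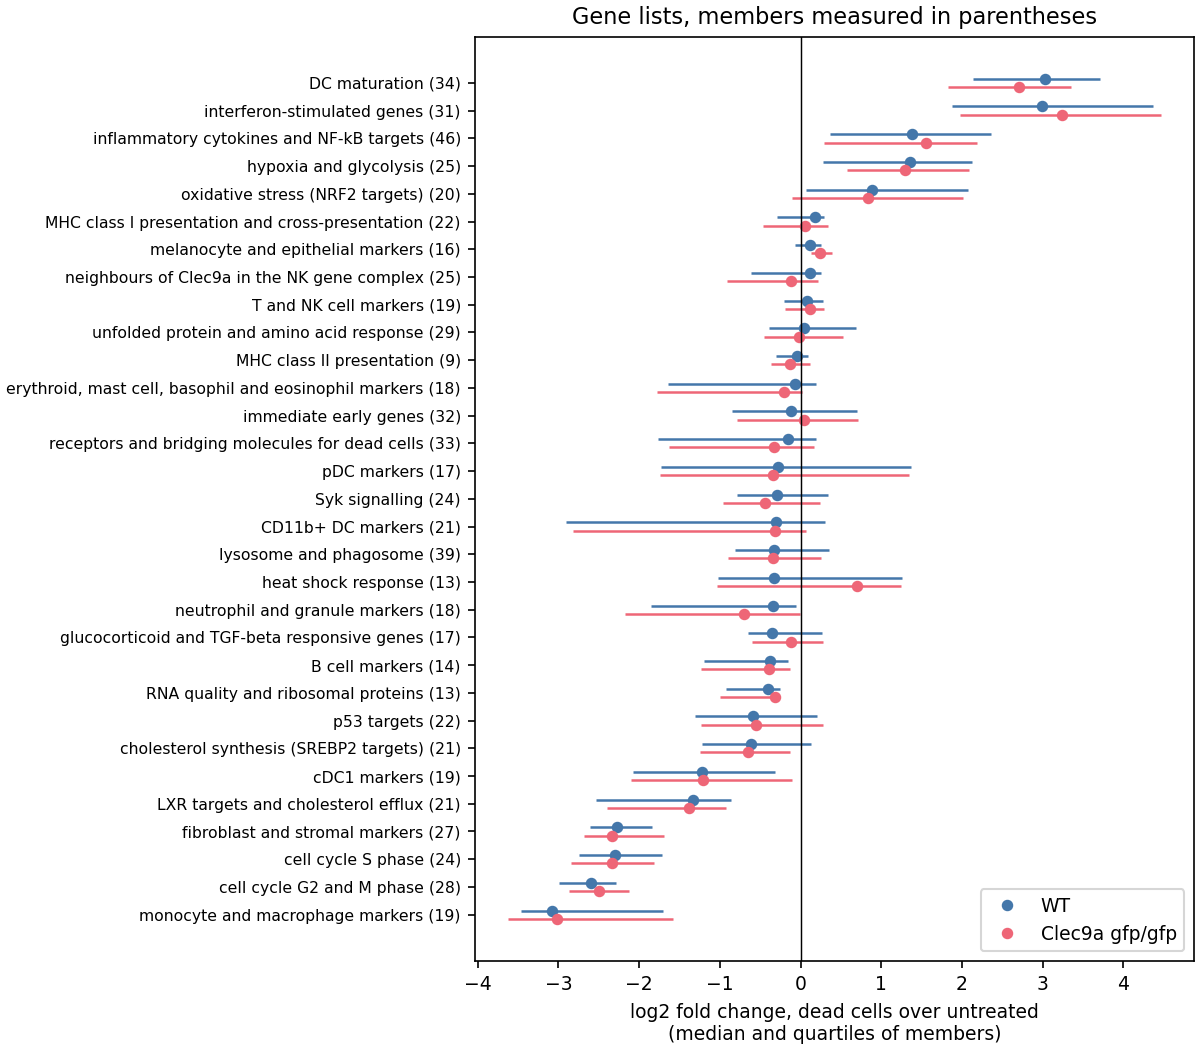
Median (point) and quartiles (line) of the log2 fold change, dead cells over untreated, of the members of each of the 31 gene lists in WT and Clec9a gfp/gfp cells. Maturation and interferon-stimulated genes lie highest and monocyte and macrophage markers lowest in both genotypes.

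The response of Clec9a gfp/gfp cells addressed what happens in the absence of DNGR-1. All 31 interferon-stimulated genes rose (median 3.23) and 33 of 34 maturation genes rose (median 2.71). Rsad2 reached 7.24 ± 0.14, Oasl1 6.95 ± 0.10, Ifit2 6.87 ± 0.30, Cxcl11 6.45 ± 0.29 and Ifit1 6.36 ± 0.31. The heat shock gene Hspa1a (5.41 ± 0.14), Gbp5 (5.40 ± 0.20), Cmpk2 (5.36 ± 0.16), Nr4a3 (5.21 ± 0.17) and the cytokine gene Il6 (5.13 ± 0.20) completed the largest rises. Of the inflammatory list 34 rose and 5 fell, and of the hypoxia list 19 rose and 3 fell (20 and 3 adjusted over the list alone). These 4 lists held with an estimated correlation, the highest adjusted p being 0.00899. The NRF2 list rose too (11 up, 4 down), as did melanocyte and epithelial markers (7 up, 0 down, median 0.24), with adjusted p = 0.463 and 0.352 with an estimated correlation.

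S phase genes (23 of 24), G2 and M phase genes (26 of 28), cDC1 markers (13 of 19, with 2 up) and LXR targets (16 of 21, with 4 up) fell in Clec9a gfp/gfp cells. Monocyte and macrophage markers (17 of 19) and stromal markers (24 of 27) fell in the same arrays. Of ribosomal proteins with other reference genes 9 of 13 fell and none rose there (median -0.32), a list that was not called. The 6 lists called lower had, with an estimated correlation, an adjusted p of 0.352, 0.352, 0.644, 0.392, 0.352 and 0.644. Cpa3 (-4.81 ± 0.41), Stab1 (-4.75 ± 0.18), F13a1 (-4.67 ± 0.14), Fcrls (-4.63 ± 0.18) and Mrc1 (-4.40 ± 0.24) fell most. Cxcr3 (-4.28 ± 0.20), Nxpe5 (-4.21 ± 0.14), the neutrophil granule gene Ngp (-4.13 ± 0.30), Cd93 (-4.10 ± 0.29) and the complement gene C1qa (-4.05 ± 0.23) followed. Clec9a itself, near the floor, did not pass (-0.05 ± 0.11, adjusted p = 0.738). In all 3856 rows rose and 7457 fell, against 6620 and 5643 with quantile normalization and 7454 and 6421 with a shift to one median.

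Averaged over the genotypes, 5128 rows rose and 8029 fell with dead cells. Quantile normalization gave 7973 and 6257, and a shift to one median 9250 and 6828. Requiring a 1.5-fold change left 8177 rows, 1807 higher and 6370 lower. Rsad2 (7.16 ± 0.10), Oasl1 (6.98 ± 0.07) and Ifit2 (6.84 ± 0.21) led the rises, and Cpa3 (-4.80 ± 0.29), Stab1 (-4.65 ± 0.12) and Fcrls (-4.51 ± 0.13) the falls, which also held Adora3 (-4.06 ± 0.12). The 12 lists called here were those called in Clec9a gfp/gfp cells, and the 4 that held there with an estimated correlation held here, at adjusted p = 0.0114 for interferon-stimulated genes and 0.0103 for the others.

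The genotypes responded with closely similar fold changes. Across all rows the responses had Pearson r = 0.947 and Spearman rho = 0.863, with a slope of 1.01, and r = 0.976 over single-gene rows. Genes are not independent replicates, and the responses share no array. Rows called in both were higher in both in 2560 cases and lower in both in 6820, where independent lists would give 559 and 2315, and 4 went opposite ways. Another 1197 rows were called in WT cells alone and 1929 in Clec9a gfp/gfp cells alone, which does not by itself show a difference. The median absolute difference in response among the 12510 rows called in either genotype was 0.14.

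**Figure D4:**
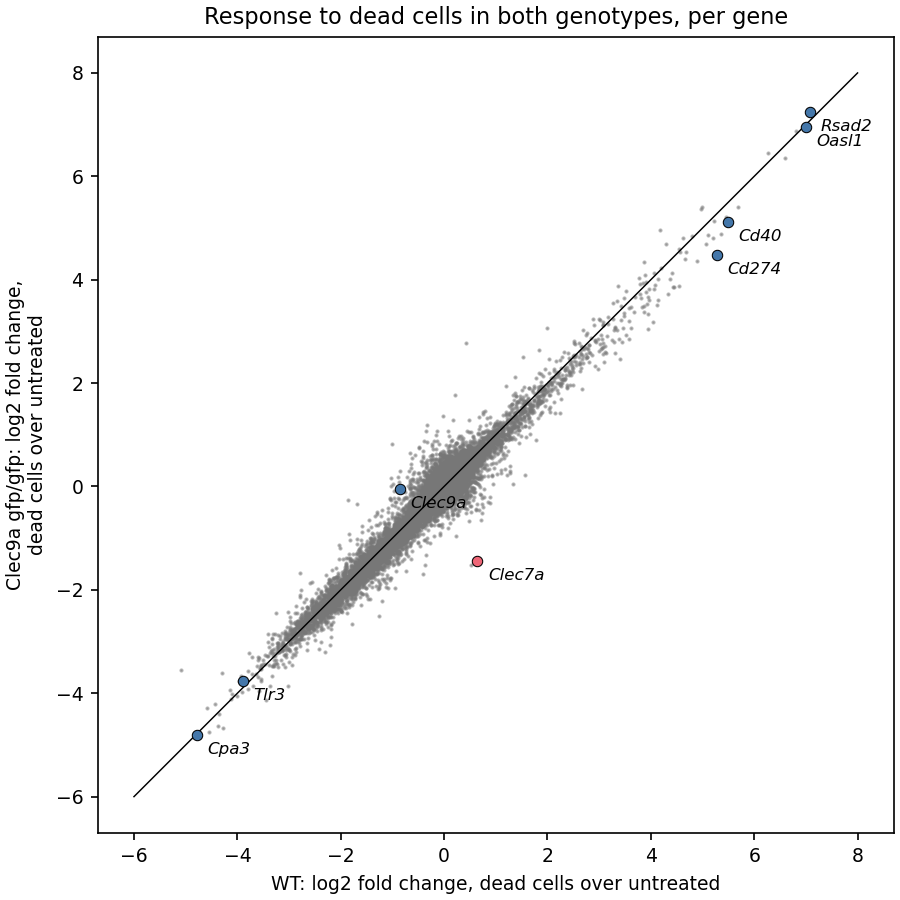
Each point is 1 gene, with the log2 fold change (dead cells over untreated) in WT cells on the x axis and in Clec9a gfp/gfp cells on the y axis; the line marks equal responses. Rsad2 and Oasl1 lie near 7 in both, and Clec7a lies at 0.64 in WT and -1.45 in Clec9a gfp/gfp cells.

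Whether DNGR-1 changes the response was tested as the difference between the responses, Clec9a gfp/gfp minus WT. A single row passed, Clec7a, which encodes the fungal glucan receptor dectin-1, at -2.09 ± 0.21 (adjusted p = 0.0219). Clec7a changed by 0.64 in WT and by -1.45 in Clec9a gfp/gfp cells. Low p-values also belonged to Cd274 (-0.82 ± 0.13, adjusted p = 0.375), Bhlhe40 (-0.89 ± 0.15, adjusted p = 0.527) and Csf2rb (-0.60 ± 0.11, adjusted p = 0.562), none of which passed. Clec9a, at 0.80 ± 0.16, did not pass (adjusted p = 0.999). Among called genes the largest differences besides Clec7a were Olfr1230 (2.36 ± 0.95), Olfr1102 (-2.03 ± 0.80), Olfr1394 (1.84 ± 0.54) and Anapc15 (1.60 ± 0.88), all with adjusted p = 0.999.

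By lists, the maturation genes were called lower in the difference, with a median of -0.26 and no member past the threshold over all rows (2 lower adjusted over the list alone). Syk signalling (median -0.14), lysosome and phagosome (-0.10) and G2 and M phase genes (0.14) were called too, with no member past it by either count. With an estimated correlation their adjusted p was 0.242 for maturation, 0.772 for Syk, 0.772 for lysosome and 0.793 for G2 and M phase. The mean response of interferon-stimulated genes differed by 0.04 (95% interval -0.22 to 0.31), that of inflammatory genes by -0.01 (-0.10 to 0.08) and that of hypoxia genes by -0.05 (-0.13 to 0.04). For maturation genes the difference was -0.27 (-0.43 to -0.11). Their mean log2 was 8.15 in Clec9a gfp/gfp and 7.89 in WT cells untreated, and 10.82 and 10.83 with dead cells, so the difference came from the untreated level and the level reached was similar. Over rows, the interval excluded a 2-fold difference in response for 75.5%. The call of Clec7a was kept without WT dead cell replicate 2 (adjusted p = 0.0457) and without Clec9a gfp/gfp untreated replicate 2 (0.00111). It was lost without each other array: WT dead cell replicates 1 and 3 (0.115 and 0.106), WT untreated replicates 1, 2 and 3 (0.107, 0.0557 and 0.0801), Clec9a gfp/gfp untreated replicates 1 and 3 (0.102 and 0.0855) and Clec9a gfp/gfp dead cell replicates 1, 2 and 3 (0.116, 0.132 and 0.121). The difference itself stayed between -2.27 and -1.99 in these 12 fits. The call was also lost with a pseudocount of 1, chosen after seeing the data (0.0639). At an unadjusted p under 0.05 in limma, 997 rows passed, fewer than the 0.05 share of all 23238 rows that would pass with no difference.

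Without dead cells, 6 rows were higher and 1 lower in Clec9a gfp/gfp cells. Clec7a, the second gene along from Clec9a in the RefSeq order, had an intensity of 3020 ± 613 against 301.2 ± 31.2 in WT cells (SD, n = 3 each), a log2 difference of 3.24 ± 0.15 (adjusted p = 4.04e-06). Bhlhe40, a transcription factor, differed by 0.99 ± 0.11 (adjusted p = 0.0124), Cd274 by 0.87 ± 0.09 (0.0121), the kinase gene Fgr by 0.90 ± 0.12 (0.0418) and Csf2rb, the shared receptor chain for GM-CSF, interleukin-3 and interleukin-5, by 0.63 ± 0.07 (0.021). The other higher row carries several gene symbols. The lower one was Clec9a.

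Several lists shifted by small amounts in untreated cells. Maturation genes had a median difference of 0.22, with 1 member higher (8 adjusted over the list alone) and Stat4 (0.79 ± 0.11, adjusted p = 0.0706), Fscn1 (0.78 ± 0.15, 0.231) and Traf1 (0.56 ± 0.10, 0.205) next to Cd274. CD11b+ dendritic cell markers had a median of 0.27, with 0 members past the threshold over all rows (5 higher and 2 lower adjusted over the list alone), and the neighbours of Clec9a 0.08, with Clec7a the 1 member called. Each of these 3 had adjusted p = 0.0321 with an estimated correlation. Called only with the preset correlation were cholesterol synthesis (median 0.18), neutrophil markers (0.18), LXR targets (0.14), pDC markers (0.11), NRF2 targets (0.10), Syk signalling (0.08), lysosome (0.06), cDC1 markers, a list that holds Clec9a, (-0.06) and G2 and M phase genes (-0.10). Their adjusted p with an estimated correlation was 0.403 or higher, and besides Fgr and Clec9a no member was called over all rows (1 more, of the NRF2 list, adjusted over the list alone). The number of rows called was 3, 2 and 3 without Clec9a gfp/gfp untreated replicates 1, 2 and 3, 4, 3 and 4 without WT untreated replicates 1, 2 and 3, and 4 without any 1 of the Clec9a gfp/gfp dead cell replicates. Without any 1 of the WT dead cell replicates it was 5 to 9, and it was 2 when only the untreated arrays were fitted. At an unadjusted p under 0.05 in limma, 1044 rows passed, again fewer than the 0.05 share of all 23238 rows that would pass with no difference.

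With dead cells the only row called by genotype was Clec9a. Clec7a was 1083 ± 32.3 against 479.1 ± 40.0 (SD, n = 3 each), a difference of 1.15 ± 0.15 that did not pass (adjusted p = 0.0614). Cd84 (0.70 ± 0.09), the thrombin receptor gene F2r (1.60 ± 0.21) and the plasminogen activator gene Plat (0.83 ± 0.11) had the same adjusted p of 0.0614. The count was 3 without WT dead cell replicate 2 and 2 without WT dead cell replicate 3, Clec9a gfp/gfp untreated replicate 2 or Clec9a gfp/gfp dead cell replicate 3. It was 5 without the dimmest 25% of rows and 5 with 1 row per gene. At an unadjusted p under 0.05 in limma, 1308 rows passed, not far above the 0.05 share of all 23238 rows that would pass with no difference. Cholesterol synthesis genes (median 0.15) and cDC1 markers (-0.09) were called, both with adjusted p = 0.982 with an estimated correlation. The cDC1 list holds Clec9a, and no other member of it was called.

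Averaged over treatments, 11 rows were higher and 1 lower in Clec9a gfp/gfp cells. Besides Clec7a (2.20 ± 0.10) and Clec9a (-6.75 ± 0.08), Cables1, Scin, Rgs9, Pecam1, F11r, Cd84, Fgr and Tcn2 were higher by 0.62 to 0.81. Bhlhe40 (0.54 ± 0.08) and Cd274 (0.46 ± 0.06), both with adjusted p = 0.0458, made up the rest. Rgs9, for example, differed by 0.71 ± 0.07 (adjusted p = 0.00981) and the SLAM family receptor gene Cd84 by 0.62 ± 0.06 (adjusted p = 0.00924). The count was 7 and 6 without WT dead cell replicates 1 and 2, 5 and 4 without WT untreated replicates 2 and 3, 5, 4 and 4 without Clec9a gfp/gfp untreated replicates 1, 2 and 3, and 5 and 3 without Clec9a gfp/gfp dead cell replicates 1 and 2. Without any other array it was 8 to 10. It was 23 without the dimmest 25% of rows and 22 with 1 row per gene. The lists called were CD11b+ markers (median 0.17), cholesterol synthesis (0.15), maturation genes (0.10), LXR targets (0.09), NRF2 targets (0.08), the neighbours of Clec9a (0.05) and cDC1 markers (-0.05, with Clec9a as the 1 member called). Their adjusted p with an estimated correlation was 0.0702, 0.385, 0.17, 0.513, 0.767, 0.0702 and 0.385.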

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

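The counts over other splits of the arrays and the tests of scale factors were set before their results were seen, and the tests on other cells, on Clec7a and on splits without the averaged genotype difference only after. The numbers of rises and falls called under each scaling, and the 2-fold numbers on the deposited scale, were known when the tests of scale factors were set.

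The difference between the genotypes' responses was past its threshold for Clec7a, at -2.09, and for 4 gene lists, with medians of -0.26 for maturation genes, -0.10 for lysosome and phagosome, -0.14 for Syk signalling and 0.14 for G2 and M phase genes. With an estimated correlation all 4 lists lost the call (adjusted p = 0.242, 0.772, 0.772 and 0.793), and the splits count rows only. Among 100 splits of genotype within treatment, drawn with the real one included, 18 called at least as many rows as the real 1, and the highest other called 12. These splits carry the averaged genotype difference, itself 12 calls, so their share does not measure chance. Once that difference was taken out of the arrays, 4 of the 100 splits called as many as the real 1 and the highest other called 1. That share lies within 1 SE of the draw from 0.05, a margin asked for only after the 4 was seen, so whether chance gives this count stays open. For the averaged comparisons the share was under 0.05, and 1 of 100 is the smallest share these splits can give. Whether the replicates were separate cultures or animals is not labelled, so the splits do not exclude chance differences between cultures. The real split alone (1 of 100) called as many rows as the 13157 for dead cells, the next reaching 5000, and 1 of 100 as many as the 12 for genotype, the next reaching 2. For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real splits called 10581 (WT response), 11313 (Clec9a gfp/gfp response), 7 (genotype untreated) and 1 (genotype with dead cells), and the highest others 0, 1, 0 and 3. As many rows as the real split were called by 1, 1, 1 and 5 of the 10 splits, the real one included.

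The first pattern is that falls of at least 2-fold outnumbered rises of that size with dead cells, averaged over genotypes, by 4456 to 826. The tables argue against a single scale factor per array as the whole cause, since after a shift of all arrays to one median the ratio of falls to rises was still 2.9 (2.74 to 3.02 without 1 array). Under quantile normalization, which removes differences that depend on brightness, it was 1.71 (1.66 to 1.72). Both lie above the bound of 1.5 set beforehand, so these scalings do not account for the whole excess, though they take away much of it. A loss of many transcripts may be a biological part of the response, and the design does not separate it from 5 h in culture. Nor was it separated from a smaller share of other cells, whose markers are taken up next.

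The second pattern is the fall of markers of macrophages and stromal cells with dead cells, in samples sorted as CD24-high, CD11b-low and B220-negative. Had all other cells been diluted alike, their markers would fall alike, but over members with a mean log2 above 8 the 13 stromal markers changed by -2.58 and the 11 macrophage markers by -3.08. The difference of 0.497 ± 0.22 (SE) was above 2 SE and just under the bound of 0.5 set for it, so it leaves this open. Within groups, stromal markers varied together between arrays, with a mean correlation of 0.609 against at most 0.284 in 1000 random lists of like brightness. Macrophage markers reached 0.276, and 14 of 1000 random lists were as high. A share of stromal cells that varied between samples would give a high correlation of stromal markers. So would shared regulation of these genes, since the random lists were matched on brightness alone. A smaller share of stromal cells with dead cells may contribute, and regulation of these genes inside the dendritic cells was not tested.

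The third pattern is Clec7a in untreated Clec9a gfp/gfp cells, 3.24 higher on the log2 scale than in WT cells. Macrophages and CD11b+ dendritic cells carry dectin-1 and would bring their other markers along, though the CD11b gate would remove most of them. The 17 such markers with a mean log2 above 8 had an upper quartile of 0.17, far below the change of Clec7a. Single markers ran from -0.56 for Ccr2 to 0.55 for Il1r2, with none past the threshold. The monocyte and macrophage list had a mean log2 of 9.69 ± 0.05 in untreated Clec9a gfp/gfp cells and 9.70 ± 0.23 in untreated WT cells (SD, n = 3 each). These close means argue against a larger share of macrophages with their usual markers as the source. The CD11b+ list, however, was called higher (median 0.27), and markers bright at baseline could hide a small share. CD11b+ dendritic cells therefore stay open as a source. Clec7a lies 2 genes from Clec9a, and 1 of 14 measured neighbours within 12 genes on either side, Clec7a itself, was called. A change of the targeted locus could reach 1 gene alone, so it cannot be told apart from a consequence of losing DNGR-1, as both come with the genotype.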

How the results depend on the processing

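The choice of pseudocounts, and the removal of rows with low IDs and no gene, were made after seeing the data, and all other alternatives before. No named gene past the threshold, in the main fit or in the alternative, changed direction. The averaged dead cell response was not part of this check. Clec9a, not called in the Clec9a gfp/gfp response, went from -0.05 to 0.18 with a shift to one median. In all 3 dead cell responses, however, falls outnumbered rises on the deposited scale and rises outnumbered falls with quantile normalization or a shift to one median. With a fold minimum of 1.5 the count for dead cells averaged over genotypes was 8177, by construction lower. The genotype counts moved most. Untreated, 7 rows became 13 with 1 row per gene, 12 with trended robust eBayes, 21 with array weights, 2 on the untreated arrays alone, 12 with pseudocount 64 and 12 without the rows of low ID. With dead cells, 1 became 3 with quantile normalization, 3 with a shift to one median, 5 without dim rows, 5 with 1 row per gene, 4 with robust eBayes, 0 with a plain log2, 2 with pseudocount 1, 5 with pseudocount 64 and 5 without the rows of low ID. Averaged, 12 became 23 without dim rows, 22 with 1 row per gene, 5 with a plain log2, 4 with pseudocount 1, 23 with pseudocount 64 and 23 without the rows of low ID. For the difference in response, 1 became 2 with robust eBayes, 2 with a plain log2, 0 with pseudocount 1 and 2 with pseudocount 64. Fewer tested rows ease the adjustment in some of these settings. For the rest the cause was not tested. Clec9a under a plain log2 was -12.31 untreated and -9.93 with dead cells, no longer past the threshold because values near 0 spread widely.

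The correlation of the responses was 0.947, with a jackknife SE of 0.00966. It was 0.969 without dim rows, 0.977 with 1 row per gene and 0.974 without the rows of low ID. A plain log2 gave 0.540, pseudocount 1 gave 0.841 and pseudocount 64 gave 0.972. The correlation was thus lower where dim rows counted more, and whether their noise is the cause was not tested. Lists called numbered 11, 12, 12, 12, 2, 7 and 4 in the order WT response, Clec9a gfp/gfp response, averaged response, genotype untreated, with dead cells, averaged, and difference in response. With an estimated correlation they numbered 4, 4, 4, 3, 0, 0 and 0. With fry, which does not compare a list with other genes, they numbered 26, 28, 28, 4, 1, 5 and 0. Under a plain log2 the genotype lists with dead cells numbered 1. Fry also gave directions opposite to camera's for lists that camera did not call. In WT cells these were lysosome (median -0.33), MHC class II (-0.0484), Syk signalling (-0.29), the neighbours of Clec9a (0.12) and erythroid, mast cell, basophil and eosinophil markers (-0.0653), and in Clec9a gfp/gfp cells MHC class I (0.0592) and MHC class II (-0.126).

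Leaving out 1 array gave 9525 to 10804 rows for the WT response, 10261 to 11521 for the Clec9a gfp/gfp response, 12474 to 13180 averaged, 2 to 9 for genotype untreated, 1 to 3 with dead cells, 3 to 10 averaged and 0 to 2 for the difference in response. Clec9a stayed between -7.21 and -7.04 untreated and between -6.43 and -6.29 with dead cells, the correlation between 0.935 and 0.945 and the shared calls between 8651 and 9310. Lists called ranged over 11 to 13, 11 to 12, 11 to 12, 10 to 13, 0 to 5, 6 to 11 and 2 to 8. For genotype with dead cells, 2 lists became 0 and 4 without WT dead cell replicates 1 and 3, and 5 and 1 without Clec9a gfp/gfp dead cell replicates 1 and 3. For genotype averaged, 7 became 11 without WT dead cell replicate 3. For the difference in response, 4 became 2 without WT dead cell replicate 3, Clec9a gfp/gfp untreated replicate 1 or Clec9a gfp/gfp dead cell replicate 2, and 8 without Clec9a gfp/gfp dead cell replicate 1. Clec7a untreated passed in all 25 alternatives (3.06 to 3.51), Cd274 in 18, Bhlhe40 in 19, Csf2rb in 13 and Fgr in 10. Clec7a passed in 12 of 24 for the difference in response.

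The replicate numbers did not pair the arrays. Of 18 same-numbered pairs of arrays from other groups 3 had deviations correlated above 0.1 and 8 below 0, and 4 of 12 arrays were closest to one of their own number. With the replicate number as a block, 3 rows were called for genotype untreated, 6 averaged and 0 for the difference in response (Clec7a at adjusted p = 0.0933, over its alternatives 0.00111 to 0.132), and 10282 and 11014 for the responses. Rows near the floor limit what low signals show.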

Other observations

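The 12 gene families tested here were chosen after seeing the data, by symbol, the correlation test of a partial response was set before its result was seen, and the test of it by list after. Several families moved with dead cells in both genotypes. Some of their members, among them Socs2, Tnfsf9, Tlr3 and Tlr11, are also in the fixed lists, so these families in part restate them. All 7 measured Schlafen genes, an interferon-responsive family, rose in WT cells, with a median log2 fold change of 2.93 (3.12 in Clec9a gfp/gfp cells) and adjusted p = 0.0245 with an estimated correlation. Slfn8, Slfn1 and Slfn4 rose most, by 3.90 ± 0.14 (SE), 3.88 ± 0.18 and 3.69 ± 0.28. Of 8 suppressors of cytokine signalling 5 rose and 1 fell, led by Cish at 4.06 ± 0.23 and Socs2 at 3.04 ± 0.27. Of 9 tumour necrosis factor ligands 6 rose and 2 fell, led by Tnfsf15 at 4.40 ± 0.21 and Tnfsf9 at 2.88 ± 0.18. With an estimated correlation the adjusted p was 0.0562 and 0.0816.

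Of 12 Toll-like receptor genes 9 fell and 1 rose in WT cells. Tlr3, Tlr12, Tlr11 and Tlr4 changed by -3.89, -3.56, -3.25 and -3.19, and Tlr9 was the one that rose, by 1.80. The median of the family was -1.10, or -0.66 with 7 members falling under quantile normalization. Of 68 mitochondrial ribosomal proteins 58 fell (median -1.38), of 27 complex I subunits 25 fell (-0.90), of 21 RNA polymerase subunits 17 fell (-1.49) and of 34 proteasome subunits 24 fell (-0.45). With that normalization the medians were -0.85, -0.48, -1.02 and -0.21, and 51, 17, 14 and 14 members fell. Adjusted p with an estimated correlation was 0.181 for Toll-like receptors and 0.151, 0.0816, 0.181 and 0.523 for the others. The 717 olfactory receptor genes had a median of 0.08, with 45 higher and 6 lower and adjusted p = 0.00292. Camera compares a list with the other genes, and the median over all single-gene rows was -0.09. With quantile normalization the family had a median of 0.13, and all rows had 0.10. The small shift therefore does not by itself show a response of these genes. Chemokine receptors (3 higher and 7 lower of 20, adjusted p = 0.914 with an estimated correlation), histone methyltransferases and demethylases (7 and 10 of 25, 0.766) and amino acid and sugar transporters (12 and 13 of 62, 0.181) were the other families tested.

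Maturation genes were somewhat higher in untreated Clec9a gfp/gfp cells. A hypothesis is that these cells were already part of the way along the dead cell response. Then the untreated genotype difference should run parallel to the Clec9a gfp/gfp response over other genes as well. Across 14770 genes outside the maturation list the correlation was -0.104, ranging from -0.173 to -0.044 without 1 array. In 100 simulations with no genotype effect it was -0.102 to -0.053, since the untreated Clec9a gfp/gfp arrays enter both with opposite sign. The covariance was -0.0178 against a simulated mean of -0.0136. The simulations drew each gene alone and so hold no variation shared by the genes of an array. Without WT untreated replicate 3 the correlation lay above their range, but that range was drawn for 3 arrays in every group. Genes called higher in the Clec9a gfp/gfp response had a median genotype difference of -0.04 and those called lower 0.03, and Spearman rho was -0.215, which the shared arrays also lower. Because the simulations lack variation shared by the genes of an array, the correlation leaves the hypothesis open.

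If untreated Clec9a gfp/gfp cells had gone as far along the whole response as their maturation genes had, other rising lists would be higher too, in proportion to their WT response. The mean of interferon-stimulated genes would need a difference of 0.30 and had -0.06 (observed minus needed -0.36, 95% interval -0.70 to -0.02). Inflammatory genes outside the maturation list would need 0.13 and had -0.01 (-0.134, interval -0.23 to -0.04). Hypoxia genes would need 0.11 and had 0.06 (-0.0466, interval -0.15 to 0.05). The data thus argue against a partial response of the interferon and inflammatory genes in this proportion, while for hypoxia genes it stays open.

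S100a8 varied widely within a group. It was at an intensity of 310 in Clec9a gfp/gfp untreated replicate 2, against 10250 and 19200 in the other arrays of that group and 7170 to 12550 in untreated WT cells.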
